A study of Saccharomyces cerevisiae with 50 samples.

How the data were processed

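The data were the deposited values of 50 two-colour hybridizations to spotted arrays of ORF and intergenic PCR products. Per the series' design text, DNA of non-replicating and of replicating or re-replicating cells was labelled with the dyes Cy3 and Cy5. The authors set the mean ratio of each array to the DNA content measured by flow cytometry. The deposited unit was the log2 ratio of the replicating to the reference channel, and the mean linear ratio of each array matched the DNA content in its title to within 0.0081. The labels mark 4 arrays in 2 groups as dye-swapped, and per the labels their deposited values had already been inverted. Scanner settings, background subtraction and spot filters were not given in the sources used here, and signal over background was not used.

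Groups were taken from the source names, which give the phase, the strain and the reference strain. The labels give no replicate numbers, so replicates were numbered in accession order. Titles add the hybridization batch (22), the print run (6), hydroxyurea, times and the numbers 35 and 23, read as temperatures in °C. Per the series' design text, most experiments had 2 hybridizations from each of 2 DNA preparations and some had 2 from 1. The labels do not say which arrays shared a preparation, so arrays were the units of every test. Whether a reference preparation served several groups was not given in the sources used here.

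Each array had 14040 elements, of which 12401 had a value on at least 1 array and 6824 to 11467 per array. The median of each array was subtracted, so that every value is relative to the bulk of the genome and says nothing on total DNA. The deposited values and labels used here gave no coordinates of the elements and named no genome build. The fallback fixed before the data were examined was therefore used, in which elements were placed by the systematic ORF name they carry and averaged over runs of 5 ORFs in name order along an arm, with at least 3 elements. The gene table of the RefSeq assembly R64 was used only for symbols and neighbour order, since its positions could not be matched to a build of the array. In it 5801 of 5809 neighbouring pairs stood in the order of their names. This gave 1190 runs with a mean from 11041 placed elements. Windows in kb, peaks and distances to origins were therefore not computed.

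All 50 arrays entered 1 limma fit with a mean for each of 15 groups, and 29 comparisons were taken from it, namely 15 profiles against the array median, 13 differences and 1 difference of differences. A run was called at a Benjamini-Hochberg (BH) adjusted p under 0.05 and at least 1.1-fold. Groups of 2 arrays borrowed their spread from all groups. The level of the ARS317 region, the spread over runs and the correlation with the A364a S-phase profile were taken per array, and groups of 4 were compared by exact permutation of the arrays over all 70 splits, where the smallest possible p is 0.0286. BH was applied over the 10 comparisons of a measure. For that correlation each A364a array was set against the mean of the other A364a arrays, and the 2 comparisons that involve A364a count in its family of 10 but are not reported. Similarity between group means was tested with 10000 circular shifts along the genome, over 105 pairs. Before each shift the chromosomes were put in random order, each in random orientation. The resulting p value is called the shift p.

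Lists were fixed in advance. They were the ARS317 region (24 elements), the mating cassettes (2 elements, both at HMRA1 in that region), engineered and marker loci (22), elements beside early (8) and late (9) origins, chosen from textbook origins by ORF name, centromere-proximal ORFs (293), subtelomeric ORFs (21), rDNA-linked ORFs (7) and the mitochondrial genome (54). The lists of origin names and of the 2-micron plasmid had 0 elements on the array and were not tested. Members were called by limma on single elements, adjusted over all elements and over the list alone. Each list was also tested with camera, with a preset correlation of 0.01 and with an estimated correlation, adjusted over 261 tests. A list was said to hold when it passed with the estimated correlation too.

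Runs are named by the rule fixed at the start. In each comparison they are the 10 highest and 10 lowest called runs with the same direction in every array, or with separate array values between groups, skipping 3 runs on each side of one taken. The text gives some of these. For comparisons with OMC, where chromosome XI filled the list, the rule was run again without that chromosome, a choice made after its values were seen. ARE1 and CDC50 are compared across all groups for the same reason.

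In a test with simulated changes added to arrays of the same design, limma recovered 89.7%, 100% and 100% of runs changed by 0.2, 0.3 and 0.5 log2 in the comparison of OMC S phase with and without re-replication, with 0.1% false calls. With 2 arrays per group, for cdc7-1 at 35 °C, it recovered 79.4%, 98.5% and 97%, with 0.71% false calls. For the ARS317 deletion it recovered 80.9%, 97% and 98.5%, with 0.4% false calls. The simulated noise was independent between arrays, without batch effects, and only 990 of 1190 runs were left unchanged. Recovery would be lower where few runs change, so 0 calls with 2 arrays per group do not exclude changes of these sizes. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.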

Results

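The series held 50 two-colour hybridizations of budding yeast genomic DNA, in 15 groups of which 10 had 4 arrays and 5 had 2. On each array, DNA of cells in S phase or of re-replicating cells was set against DNA of non-replicating cells, so that a higher ratio stood for more copies of a locus. Per the labels, the S-phase DNA came from the wild types S288c and A364a and from a strain called OMC, each compared with its own G1 DNA. Re-replicating DNA of the strains OMC, OC and MC2A, taken in G2 or after release from G1, was compared with DNA of strains called OM, O and M. The letters were read as mutations in ORC, MCM and CDC6, which the series' design text names. Copy number was followed along the chromosomes as the mean log2 ratio of runs of 5 neighbouring ORFs over the array median, and each run is named here by a gene in it. Highest and lowest runs are those among the called runs with the same direction on every array, or with separate array values between groups. Values are group means with the limma standard error for runs and with the standard deviation between arrays for other measures. Hybridizations came partly from shared DNA preparations, which the labels do not identify, so the p values partly measured technical spread.

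In wild-type S phase, the DNA near centromeres and near early origins had the most copies. In S288c, 257 of 267 centromere-proximal elements and 7 of 7 elements beside early origins rose, with medians of 0.47 and 0.57 log2. In A364a, 241 of 273 and 8 of 8 rose, with medians of 0.40 and 0.51. The lists held with an estimated correlation, at adjusted p = 1.2e-05 and 2.5e-04 in S288c and adjusted p = 8.3e-05 and 0.0017 in A364a. The runs furthest above the median in S288c were those of STP22 (0.66 ± 0.04), an ESCRT component gene beside the chromosome III centromere, of DAL4 (0.64 ± 0.03), which encodes the allantoin permease, and of BIK1 (0.62 ± 0.03), a microtubule-binding protein gene. Those furthest below were PDR17 (−0.41 ± 0.03) and SIP4 (−0.40 ± 0.03). In A364a the highest were PES4 (0.58 ± 0.04), HXT6 (0.58 ± 0.04), a hexose transporter gene, and HOG1 (0.57 ± 0.03), the osmotic stress kinase gene. The lowest was BNA2 (−0.36 ± 0.04). Elements beside late origins had a median of −0.20 in S288c, where 7 of 9 fell, but the list did not hold with an estimated correlation (adjusted p = 0.149). Of 1186 runs in S288c, 413 were higher and 446 lower than the array median, and of 1187 in A364a, 383 were higher and 405 lower (limma, 4 arrays each, adjusted p under 0.05 and at least 1.1-fold). Centred on the mean ratio, the A364a counts were 307 and 526.

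The backgrounds differed at particular places rather than in the general layout. The profiles correlated at r = 0.91 over 1185 runs. The shift p was 1e-04, the smallest possible with 10000 shifts (BH 1.8e-04 over 105 pairs of profiles), and runs are not independent replicates. A364a was lower than S288c at KRE9 (−0.61 ± 0.04), a cell wall glucan gene, at MPS3 (−0.55 ± 0.06), a spindle pole body gene, and at EAF5 (−0.40 ± 0.05). It was higher at CNA1 (0.31 ± 0.04), a calcineurin subunit gene, and at RPL12B (0.30 ± 0.04). In all, 68 runs were higher and 125 lower of 1185 (16.3%). With the hybridization batch as a fixed block, 0.34% were called. The single shared batch had 1 array of each background, and its profile difference correlated at r = 0.60 with that of the other arrays. Per the titles, the S288c arrays mixed hydroxyurea treatment with a timed sample, and the A364a titles named a time alone. The hydroxyurea arrays of S288c correlated with the A364a profile at a mean of 0.86 and the timed arrays at 0.93. The share of the treatment in the differences between the backgrounds was not tested.

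The OMC strain without induced re-replication had lower S-phase ratios around early loci than its A364a background. The spread over runs was 0.20 ± 0.01 against 0.24 in A364a (exact p = 0.0571, BH 0.0635 over 10 tests, which missed the threshold). Relative to A364a, 117 of 266 centromere-proximal elements and 4 of 8 elements beside early origins fell, with medians of −0.18 and −0.27 (adjusted p = 0.00997 and 0.0156 with an estimated correlation). The runs that fell most were PEX35 (−0.63 ± 0.04), a peroxisomal gene, THS1 (−0.50 ± 0.04), the threonyl-tRNA synthetase gene, and AGP1 (−0.46 ± 0.04), an amino acid permease gene. FAU1 (0.29 ± 0.03) and HLR1 (0.28 ± 0.03) rose most. In OMC itself the highest runs were BUD31 (0.46 ± 0.04) on the right arm of chromosome III and TRP1 (0.41 ± 0.04), beside an early origin on chromosome IV, and the lowest was GLG1 (−0.40 ± 0.06). The OMC profile had 324 runs higher and 355 lower of 1188, with 63.6% of 275 centromere-proximal elements up (median 0.20, adjusted p = 0.0163 with an estimated correlation) and 5 of 8 beside early origins (0.28, adjusted p = 0.0395 with an estimated correlation). Between the strains 121 runs were higher and 200 lower of 1187. The split depended on the centre, since with the mean ratio as centre 196 were higher and 136 lower. Per the titles, the OMC arrays were from hydroxyurea and the A364a arrays were not so named, and the groups shared no hybridization batch.

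Induced re-replication during S phase raised already early regions much further. All arrays with and without induction were from hydroxyurea, per their titles. The run of HOG1 stood at 1.56 ± 0.03 log2 in OMC with re-replication, 2.94-fold over the array median, followed by PDX1 (1.38 ± 0.04), CCT8 (1.37 ± 0.04), a chaperonin subunit gene, CRF1 (1.30 ± 0.04), in a run that also holds the histone genes HTA1 and HTB1, and YUH1 (1.29 ± 0.02). Against OMC S phase without induction HOG1 rose by 1.23 ± 0.04, PDX1 by 1.08 ± 0.06, CRF1 by 0.96 ± 0.06 and YUH1 by 0.96 ± 0.04. Elements beside early origins rose in 7 of 8 cases (median 0.79, adjusted p = 5.8e-09 with an estimated correlation), and 68.4% of 275 centromere-proximal elements rose (0.26, adjusted p = 0.0287 with an estimated correlation). KIN4 (−0.42 ± 0.04), a mitotic checkpoint kinase gene, and CAR2 (−0.39 ± 0.04) fell most. In the induced group's own profile all 8 elements beside early origins (0.99, adjusted p = 5.8e-09 with an estimated correlation) and 274 of 282 centromere-proximal elements (0.48, adjusted p = 5e-04 with an estimated correlation) were up, and PTP2 was lowest (−0.26 ± 0.03). The mean profiles with and without induction correlated at r = 0.71 over 1185 runs. Correlation with the A364a profile was 0.79 ± 0.02 with induction and 0.81 ± 0.04 without (exact p = 0.629, 4 arrays each), while the spread over runs grew from 0.20 ± 0.01 to 0.32 ± 0.05 log2 (exact p = 0.0286, BH 0.0408 over 10 tests).

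Of 1188 runs, 500 differed between OMC with and without induced re-replication, 346 of them higher with it. The induced profile had 339 higher and 318 lower of 1189. These splits rested on the median as centre. With the mean ratio as centre, which moved the induced arrays by −0.16 log2, 144 runs were higher and 429 lower between the groups, and 215 higher and 683 lower in the induced profile. The induced arrays fell in 2 batches that shared none with the uninduced arrays. The ARS317 region stood at 0.07 ± 0.19 with induction and −0.11 ± 0.05 without (exact p = 0.143).

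When re-replication was induced in G2, the OMC strain had raised ratios on all of chromosome XI, at both ends of chromosome III and at many runs elsewhere. Whether the induced cells or the reference carried the difference on chromosome XI was not settled. The ARS317 region at the right end of chromosome III, which holds the silent mating cassette HMR, stood at 0.68 ± 0.11 log2 (1.60-fold, 4 arrays), and 23 of its 24 elements rose (median 0.72, adjusted p = 0.0225 with an estimated correlation). Both HMRA1 elements rose (0.75, adjusted p = 0.0114 with an estimated correlation). The run of GIT1, a glycerophosphoinositol permease gene, rose by 0.77 ± 0.05, YCL076W at the opposite end of chromosome III by 0.95 ± 0.05, and UPA2 on chromosome XIII by 0.80 ± 0.03. Inside the arms, RGT2 on chromosome IV rose by 0.67 ± 0.03 and BUD31 on chromosome III by 0.56 ± 0.04. Without chromosome XI and the outermost 3 runs of each arm, 197 of 1071 runs were higher and 213 lower. On chromosome XI all 66 runs were higher, among them MSN4 (1.07 ± 0.07), a stress transcription factor gene, NFT1 (1.02 ± 0.05) and TFA1 (0.95 ± 0.08). The median of that chromosome was 0.73 ± 0.07. Among called runs below the median on all 4 arrays, CIK1 (−0.31 ± 0.03) and RPS0B (−0.31 ± 0.04) were lowest. Centromere-proximal DNA was not generally raised, with 36 of 290 elements up and 41 down, and the correlation with the A364a S-phase profile was 0.06 ± 0.04. Beside early origins 4 of 8 elements rose and 0 fell (median 0.12, adjusted p = 0.343 with an estimated correlation), and beside late origins 4 of 9 rose (0.15, adjusted p = 0.0648 with an estimated correlation). Of 18 subtelomeric elements 7 rose and 5 fell (adjusted p = 0.651 with an estimated correlation). In all 294 runs were higher and 218 lower of 1189, or 228 and 218 without chromosome XI. Centred on the mean ratio, 229 were higher and 468 lower.

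**Figure D1:**
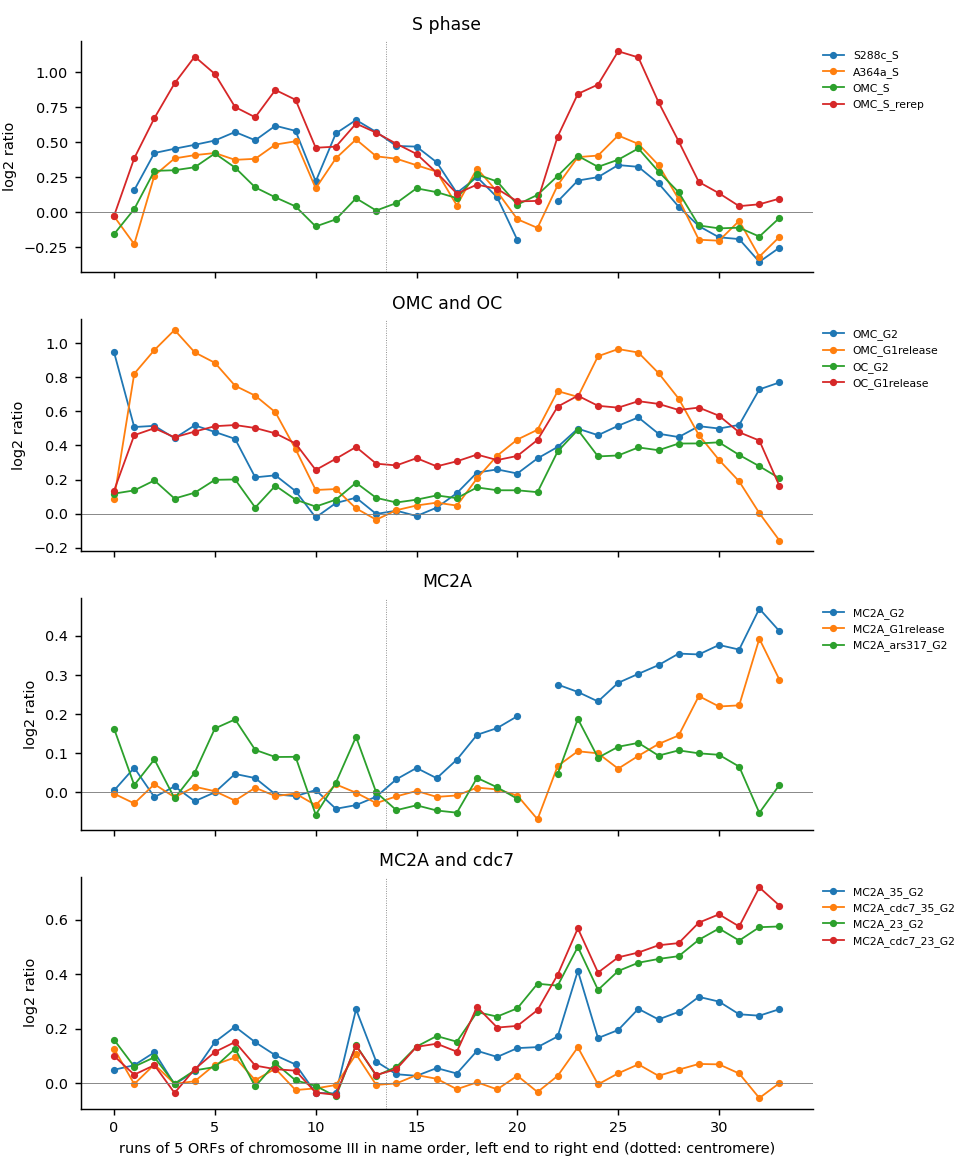
Copy number along chromosome III. Each point is the group mean of a run of 5 ORFs, as log2 ratio over the array median, drawn from the left to the right end in the order of systematic names, with the centromere dotted. Panels group the S-phase groups, OMC and OC, MC2A with and without ARS317, and MC2A with and without cdc7-1. Gaps are runs without a group mean. The panels have different vertical scales.

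After release from G1, the same strain had more DNA beside early origins than in G2. PCF11, a cleavage factor gene beside SIR4 on chromosome IV, stood at 1.21 ± 0.04 log2, YUH1 at 1.17 ± 0.02, SPB1 on the left arm of chromosome III at 1.08 ± 0.04, YPP1 at 1.07 ± 0.03 and HOG1 at 0.94 ± 0.03. The lowest runs were DNF2 (−0.82 ± 0.10), a phospholipid flippase gene, the chromosome-end runs of MAN2 (−0.80 ± 0.03) and MAL31 (−0.78 ± 0.04), the maltose permease gene, and DAK2 (−0.69 ± 0.03). Against G2, PCF11 rose by 0.95 ± 0.05, VMA3 by 0.86 ± 0.06 and HOG1 by 0.84 ± 0.04, while BDS1 (−0.95 ± 0.03), GIT1 (−0.93 ± 0.08), DAK2 (−0.90 ± 0.04) and MAL31 (−0.90 ± 0.05) fell. Elements beside early origins rose against G2 in 5 of 8 cases (0.28, adjusted p = 0.0287 with an estimated correlation) and those beside late origins fell in 6 of 9 (−0.50, adjusted p = 0.0119 with an estimated correlation). In the ARS317 region 22 of 24 elements fell (−0.69), though the list did not hold with an estimated correlation (adjusted p = 0.129). The region's level was 0.01 ± 0.12, lower than in G2 by 0.67 (exact p = 0.0286, BH 0.0571 over 10 tests, which missed the threshold). Centromere-proximal elements rose in 163 of 290 cases against G2 (0.24, adjusted p = 0.0609 with an estimated correlation).

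The correlation with A364a S phase was 0.48 ± 0.08 after G1 release, higher by 0.42 than in G2, and the spread was 0.37 ± 0.03 against 0.26 ± 0.01 (exact p = 0.0286 and BH 0.0408 over 10 tests for each). In the batch that held both stages, with 1 array each, the correlations were 0.41 and 0.09, the spreads 0.39 and 0.26, and the ARS317 region differed by −0.87. Between the stages 372 runs were higher and 433 lower of 1189, or 368 and 385 without chromosome XI. The G1-release profile had 409 higher and 428 lower, or 352 and 428 without chromosome XI, and 290 and 523 with the mean ratio as centre. In it 6 of 8 elements beside early origins rose (0.57, adjusted p = 0.0032 with an estimated correlation), and 184 of 292 centromere-proximal elements (0.29, adjusted p = 0.129 with an estimated correlation). The G1-release arrays split by dye order, which went with the batch. The median of chromosome XI was 0.85 ± 0.01 on the 2 arrays of usual dye order and 0.05 ± 0.02 on the 2 dye-swapped arrays. The ARS317 region stood at −0.0686 and −0.116 on the former and at 0.104 and 0.116 on the latter, the correlation with A364a S phase at 0.408 and 0.407 against 0.549 and 0.552, and the centromere-proximal median at 0.20 and 0.23 against 0.31 and 0.32.

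**Figure D2:**
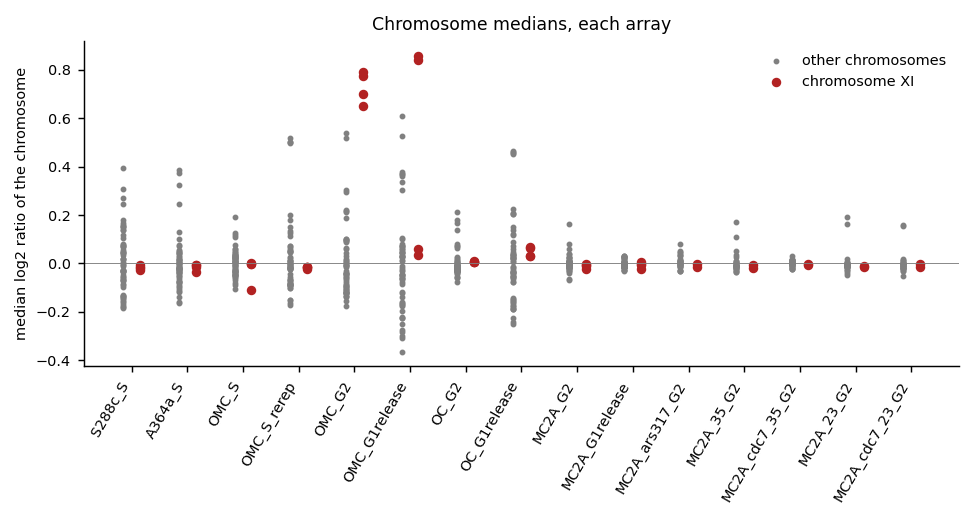
Median log2 ratio of each chromosome on each array, by group. Chromosome XI is red and the other chromosomes are grey. It was raised on all 4 arrays of OMC in G2 and on 2 of 4 arrays of OMC after G1 release.

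In the OC strain, whose name lacks the M, the runs called in G2 lay mainly on chromosome III. Of 22 called runs, all higher, 13 lay on the right arm and 5 on the left arm of that chromosome, and 4 on chromosome X. The highest was the run of ARE1 (0.49 ± 0.05), an acyl-CoA sterol acyltransferase gene in the middle of the right arm, then TUP1 (0.42 ± 0.04), a general repressor gene, CDC6 (0.25 ± 0.03) and GID7 (0.20 ± 0.04). In the ARS317 region 17 of 24 elements rose, or 22 adjusted over the list alone, with a median of 0.30 (adjusted p = 0.0064 with an estimated correlation). The tested runs numbered 1189 (limma), of which 348 had an unadjusted p under 0.05, 194 of them lower, so smaller changes elsewhere were not ruled out. With the mean ratio as centre 21 were higher and 4 lower. The called share of 1.85% rose to 5.38% with a dye term in the model and to 2.78% with elements measured on at least 45 arrays.

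After release from G1, OC gained early-replicating DNA as well. Of 290 centromere-proximal elements 183 rose (0.20, adjusted p = 0.0281 with an estimated correlation), and 7 of 8 beside early origins (0.38, adjusted p = 8.9e-04 with an estimated correlation). ARE1 (0.69 ± 0.05), ATG15 (0.64 ± 0.04), a vacuolar lipase gene, GID7 (0.52 ± 0.05) and SOD1 (0.47 ± 0.03), the copper-zinc superoxide dismutase gene, were highest. NBP1 (−0.51 ± 0.05), HPR1 (−0.51 ± 0.03) and MAN2 (−0.50 ± 0.02) were lowest. Against G2, LSB5 (0.47 ± 0.05), YUH1 (0.39 ± 0.04) and PCF11 (0.35 ± 0.05) rose most, and GAC1 (−0.45 ± 0.03), HIS3 (−0.43 ± 0.04) and MAL31 (−0.41 ± 0.04) fell. Centromere-proximal elements rose in 47.8% of 289 cases against G2 (0.21, adjusted p = 0.00945 with an estimated correlation) and those beside early origins in 5 of 8, or 8 adjusted over the list alone (0.31, adjusted p = 0.0036 with an estimated correlation). The ARS317 region stood at 0.37 ± 0.06 against 0.30 ± 0.06 in G2 (exact p = 0.143), with 18 of 24 elements up after release (0.43, adjusted p = 0.183 with an estimated correlation). The G1-release profile had 293 runs higher and 352 lower of 1189, and the stages differed at 282 higher and 322 lower. The correlation with A364a S phase was 0.40 ± 0.01 against 0.14 ± 0.03 and the spread 0.23 against 0.07 (exact p = 0.0286 and BH 0.0408 over 10 tests for each). In the shared batch the correlations were 0.40 and 0.12.

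**Figure D3:**
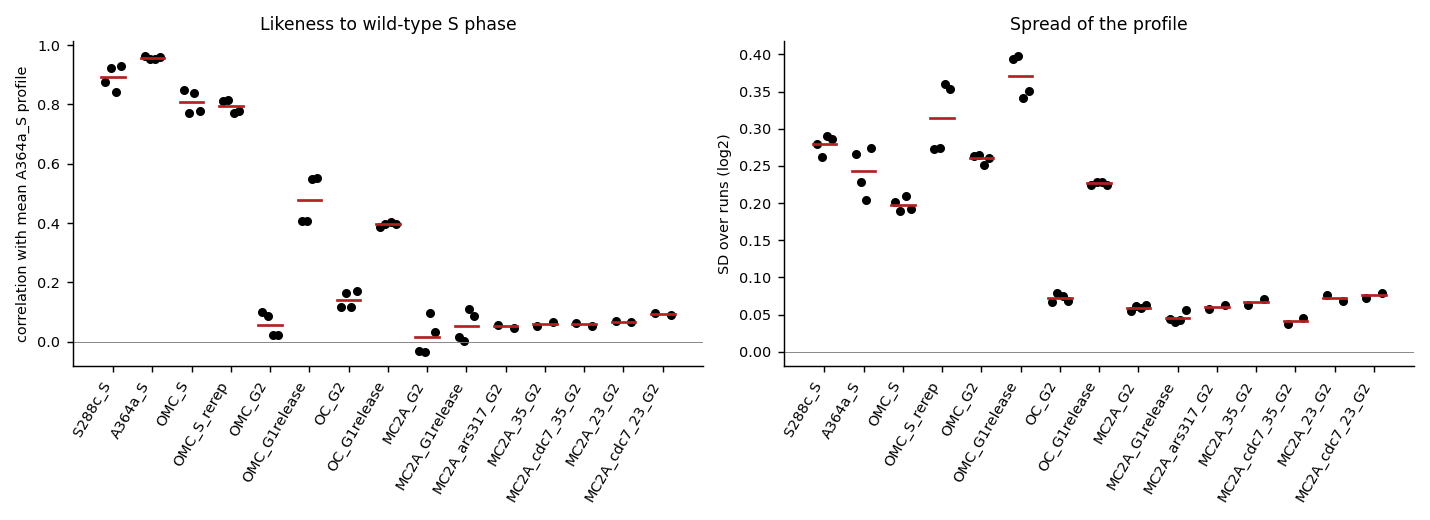
Shape of the profiles on each array, by group. Left, correlation of the array with the mean A364a S-phase profile, where each A364a array was set against the mean of the others. Right, standard deviation of the log2 ratio over runs of 5 ORFs. Red bars are group means.

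In MC2A, the runs called in G2 lay almost all on the right arm of chromosome III. Of 1187 runs 17 were higher and 0 lower (100 runs at unadjusted p under 0.05, limma), and 15 of the 17 lay on that arm. Levels climbed towards the end, from TAF2 (0.28 ± 0.04) and SOL2 (0.35 ± 0.04) to CDC50 (0.47 ± 0.05), a flippase subunit gene whose run also holds HMRA2. Its ARS317 region averaged 0.43 ± 0.10, and 21 of 24 elements rose, or 23 adjusted over the list alone (median 0.42, adjusted p = 5.0e-11 with an estimated correlation). Off the arm, the called runs were those of CDC6 (0.19 ± 0.03) and SEC61 (0.15 ± 0.03), the translocon gene. After G1 release 7 runs were higher and 1 lower of 1189, of which 6 lay on the same arm, with CDC50 at 0.39 ± 0.05 and SOL2 at 0.15 ± 0.04. SOL4, a 6-phosphogluconolactonase gene, was lower (−0.16 ± 0.03), a change carried by an intergenic element that stood apart from its run in 8 groups. The ARS317 region was then at 0.34 ± 0.06, with 16 of 23 elements up, or 21 over the list alone (0.30, adjusted p = 4.3e-08 with an estimated correlation). The stages differed at 0 of 1187 runs (limma, 39 at unadjusted p under 0.05), and leaving out MC2A_G2 replicate 3 called 0.08%. With the batch as a fixed block 4.12% were called. That fit compared the stages only through the batch that held both, with 1 array of each. Its spread came from pairs of arrays within a batch. Neither the correlation with A364a S phase (0.05 ± 0.05 and 0.02 ± 0.06, exact p = 0.371) nor the ARS317 region (exact p = 0.171) passed between the stages. In the shared batch the region differed by −0.27. With a dye term, 5.81% of runs were called in G2 in place of 1.43%. Replicates of MC2A correlated weakly between batches, at r = 0.164 to 0.273 in G2 and 0.0186 to 0.274 after release.

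Relative to the array median, OC and MC2A in G2 differed from OMC at runs across the genome, while the ARS317 region was raised in each strain. Values centred on the median do not measure how much of the genome re-replicated. The titles give a DNA content of 2.7 for OMC in G2, and of 2.0 for OC and for MC2A. In G2, OC was lower than OMC at YCL076W (−0.83 ± 0.07), UPA2 (−0.67 ± 0.05), RGT2 (−0.58 ± 0.04), a glucose sensor gene, and GIT1 (−0.56 ± 0.07), besides chromosome XI. MC2A was lower than OMC at YCL076W (−0.94 ± 0.08), UPA2 (−0.77 ± 0.05) and RGT2 (−0.62 ± 0.04). DON1 in OC (0.25 ± 0.04) and MRPL24 in MC2A (0.33 ± 0.05) were furthest above OMC among called runs whose array values did not overlap between the groups. Of the ARS317 region's 24 elements, 17 were lower in OC than in OMC, or 19 over the list alone (−0.38, adjusted p = 0.297 with an estimated correlation), and 12 in MC2A, or 14 over the list alone (−0.22, adjusted p = 0.587 with an estimated correlation). The region's level was lower by 0.38 and by 0.25 (exact p = 0.0286 and BH 0.0571 over 10 tests for each, which missed the threshold). Within batches the differences from OMC were −0.55, −0.29 and −0.19 in OC and −0.06 in MC2A. Elements beside late origins were lower in OC than in OMC in 4 of 9 cases, or 6 over the list alone (−0.23, adjusted p = 0.0402 with an estimated correlation).

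OC and OMC in G2 differed at 403 of 1189 runs, 271 of them lower in OC, or at 338 with 205 lower without chromosome XI. MC2A and OMC differed at 493 of 1187 runs, 291 of them lower in MC2A, or at 427 with 225 lower without that chromosome. With the mean ratio as centre the counts turned to 332 higher and 194 lower in OC and 433 higher and 221 lower in MC2A. The spread was 0.07 ± 0.01 in OC and 0.06 ± 0.00 in MC2A (exact p = 0.0286 and BH 0.0408 over 10 tests for each, against OMC). The correlation with A364a S phase was higher in OC than in OMC by 0.08 (exact p = 0.0286, BH 0.0408), a call that was lost without chromosome XI, where the difference was 0.07.

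After G1 release, OC and OMC shared much of their pattern, and MC2A stood apart. The OC and OMC profiles correlated at r = 0.82 over 1185 runs (shift p = 1e-04, the smallest possible, BH 1.8e-04 over 105 pairs, runs not being independent replicates). OC was lower than OMC at CRF1 (−0.88 ± 0.06), IME1 (−0.73 ± 0.05), the meiotic inducer gene, and PDX1 (−0.67 ± 0.06), and higher at SLU7 (0.88 ± 0.13), a splicing factor gene, and CDC50 (0.43 ± 0.07). MC2A was lower than OMC at PCF11 (−1.26 ± 0.05), IME1 (−1.13 ± 0.05) and SPB1 (−1.09 ± 0.06), and higher at DNF2 (0.83 ± 0.14) and MAN2 (0.82 ± 0.03). Elements beside early origins were lower in MC2A in 6 of 8 cases (−0.45, adjusted p = 0.0081 with an estimated correlation). The ARS317 region was above OMC in 20 of 24 elements in OC (0.38, adjusted p = 0.129 with an estimated correlation), and in 15 of 23 in MC2A (0.36, adjusted p = 0.521 with an estimated correlation). The region's level was higher by 0.36 in OC and 0.33 in MC2A (exact p = 0.0286 and BH 0.0571 for each, which missed the threshold). Within batches it was higher by 0.37 and 0.55 in OC and 0.41 in MC2A. OC differed from OMC at 214 runs higher and 334 lower of 1189, or 214 and 270 without chromosome XI, and MC2A at 419 higher and 411 lower, or 419 and 359. Centred on the mean ratio, the counts were 381 and 231 in OC and 518 and 292 in MC2A. The correlation with S phase was lower than in OMC by 0.08 in OC and by 0.43 in MC2A (exact p = 0.0286 and BH 0.0408 for each). Within the 2 batches shared by OC and OMC it was 0.402 against 0.408 and 0.396 against 0.406, so the gap of OC came from the dye-swapped OMC arrays. Within the batch shared by MC2A and OMC it was 0.108 against 0.406.

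With ARS317 deleted, the extra DNA at the right end of chromosome III in MC2A was not seen. The ARS317 region stood at 0.02 ± 0.00 log2 in the 2 arrays of the deletion strain, against 0.43 ± 0.10 in the 4 arrays of MC2A with the origin. At CDC50 the difference was −0.52 ± 0.09, with a limma adjusted p of 9.0e-04. Of 23 elements in the region 7 fell, or 19 adjusted over the list alone (median −0.44, adjusted p = 3.5e-05 with an estimated correlation), and 0 rose. The HMRA1 elements had a median of −0.41, with 2 of 2 down over the list alone (adjusted p = 1.6e-04 with an estimated correlation). Over all runs 7 of 1187 were lower and 0 higher (limma), 5 of the 7 on the right arm of chromosome III, and the others at SEC20 (−0.27 ± 0.06) and SNU66 (−0.15 ± 0.03). The count was fragile. Leaving out replicate 1 or replicate 2 of the deletion strain left 0.08% of runs called in place of 0.59%, and leaving out MC2A_G2 replicate 2 or replicate 4 left 0.25%.

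The deletion strain's own profile had 11 runs higher and 1 lower of 1187, with 6 of the higher runs on the right arm of chromosome XII, and with CDC6 (0.21 ± 0.04), YRF1-2 (0.20 ± 0.05), a subtelomeric helicase gene, and RPS29A (0.18 ± 0.04) highest and SEC20 (−0.21 ± 0.05) lowest. In the ARS317 region 0 of 23 elements passed (median 0.00). Without replicate 1, 0% of runs in this profile were called, and 0.08% without replicate 2, against 1.01% with both. With the print run as a covariate 0% were called. That fit gave the profile for a print run that no deletion array used, so the drop does not show a print effect. The deletion strain and MC2A with the origin in G2 shared no hybridization batch and no print run, so the deletion cannot be told apart from these in that comparison. On the print run of the deletion arrays, MC2A at 35 and 23 °C still had the ARS317 region at 0.27 and 0.57.

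**Figure D4:**
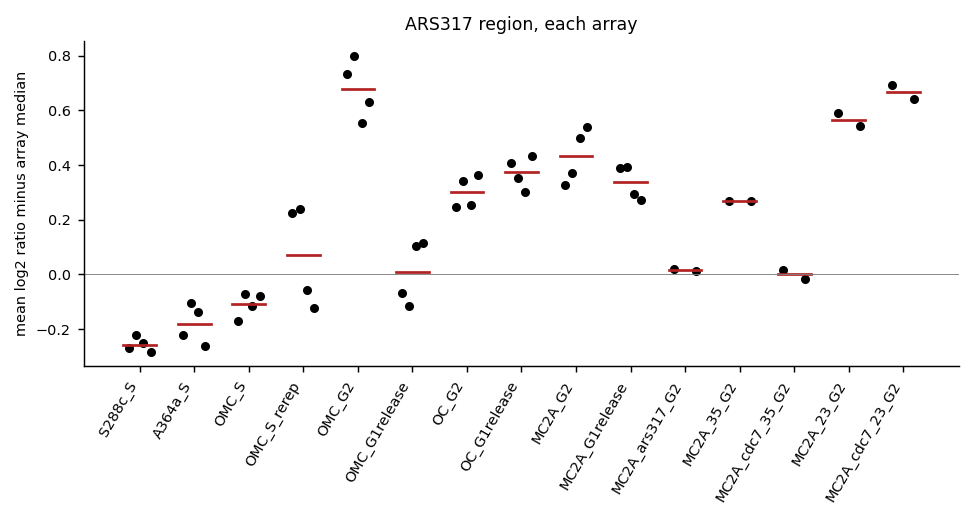
Mean log2 ratio over the array median of the elements of the ARS317 region at the right end of chromosome III, on each array. Red bars are group means of 4 or 2 arrays.

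With the cdc7-1 allele, the extra DNA at the right end of chromosome III was not seen at 35 °C and was seen at 23 °C. CDC7 encodes the kinase that triggers origin firing. The ARS317 region stood at −0.00 ± 0.02 in MC2A cdc7-1 at 35 °C, against 0.27 ± 0.00 in MC2A at the same temperature. At 23 °C the values were 0.67 ± 0.04 with the allele and 0.57 ± 0.03 without, from 2 arrays per group. At 35 °C the region's elements had a median difference of −0.26, with 0 of 22 passing over all elements and 7 adjusted over the list alone (adjusted p = 0.0054 with an estimated correlation). At 23 °C the median difference was 0.11 (adjusted p = 0.447 with an estimated correlation). The difference of the differences had a median of −0.39, with 2 of 22 elements lower over the list alone (adjusted p = 0.0095 with an estimated correlation). The HMRA1 elements are part of the region, so they are no separate evidence. They stood at −0.30 for the allele at 35 °C (adjusted p = 5.1e-05 with an estimated correlation) and −0.27 for the difference of the differences (adjusted p = 0.0229 with an estimated correlation). With the allele at 23 °C, the HMRA1 ORF element was at 0.18 against a median of 0.80 in its run. Within batches the region differed by −0.25 and −0.28 at 35 °C and by 0.08 at 23 °C.

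At 35 °C the MC2A profile had 14 runs higher and 4 lower of 1188, with ARE1 (0.41 ± 0.07), PTC6 (0.32 ± 0.05) and GIT1 (0.27 ± 0.06) highest and EPT1 (−0.18 ± 0.05) lowest. In its ARS317 region 7 of 23 elements rose, or 16 over the list alone (0.26, adjusted p = 0.0281 with an estimated correlation). The calls of this profile, 1.52% of runs, were mostly lost when either array was left out. The print run as a covariate left 0%, in a fit for a print run that no array of this group used. With the allele at 35 °C, 0 of 1189 runs were called (limma, 29 at unadjusted p under 0.05), and 0 of 22 region elements. At 23 °C, MC2A had 18 runs higher and 0 lower (100 at unadjusted p under 0.05, limma), 17 on the right arm of chromosome III, with GIT1 (0.57 ± 0.06), PTC6 (0.53 ± 0.05) and ARE1 (0.50 ± 0.07). With the allele 16 were higher and 0 lower (98 at unadjusted p under 0.05, limma), with CDC50 (0.72 ± 0.07), ARE1 (0.57 ± 0.07) and SOL2 (0.51 ± 0.05). In the region 22 of 24 and 22 of 23 elements rose, or 23 and 23 over the list alone (0.59 and 0.67, adjusted p = 1.8e-08 and 3.9e-10 with an estimated correlation). Run by run, the allele gave 0 calls at 35 °C (11 at unadjusted p under 0.05, limma), 0 at 23 °C (1 at unadjusted p under 0.05, limma) and 0 for the difference of the differences (13 at unadjusted p under 0.05, limma). The run of CDC50 differed by −0.30 ± 0.10 at 35 °C and was not called (limma adjusted p = 0.9997). With the batch as a fixed block, 1.26% of runs were called at 35 °C and 1.18% for the difference of the differences.

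Across the 261 list tests, 95 passed with the preset correlation of 0.01 and 41 of them passed with the estimated correlation. They were the tests given above with such a p under 0.05, the HMRA1 elements in the MC2A profiles with the origin and an active CDC7, and the engineered loci in MC2A after G1 release (2 of 22 up, adjusted p = 0.0133 with an estimated correlation). The CDC6 ORF was among those loci. The mitochondrial genome was below the array median in most groups, with all mitochondrial calls lost with an estimated correlation. Its largest difference was between MC2A and OMC after G1 release (0.75, 49 of 51 up, adjusted p = 0.50 with an estimated correlation). The subtelomeric and rDNA-linked lists gave no test that passed with the estimated correlation.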

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

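Apart from that of the cdc7-1 effect between temperatures, the tests in this part were chosen after the results were seen. Chromosome XI was raised along its whole length in OMC in G2 and on 2 of 4 arrays of OMC after G1 release, and in no other group. A batch or print run was excluded as the whole cause, since the highest chromosome XI median among the 8 arrays of other groups in the same batches was 0.067 log2, against 0.73 ± 0.07 in OMC in G2. Dye order was excluded too, as the unswapped arrays of MC2A after G1 release differed from its swapped arrays by 0.011. Extra copies of the whole chromosome in the re-replicating cells, or fewer in the reference strain, could account for the pattern, because the difference of 0.755 between the OMC arrays was flat, with a standard deviation over runs 0.832 times the median of the other 15 chromosomes. That test does not separate the induced cells from the OM reference, so which of them carried the change stays open.

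The elements of CDC6 and of the neighbouring ORF YJL195C were raised wherever a strain with C was compared with a strain without it. The lowest group mean of these 3 elements was 0.61 log2 and the highest 0.869 over 11 groups, while OMC in S phase, compared with its own DNA, stood at 0.13 and −0.03. Re-replication at the locus was excluded as the cause in OC in G2 and the MC2A groups, where the 6 neighbouring elements had a mean of 0.022 (standard deviation 0.044 over 8 groups). A further copy of CDC6 sequence in the strains with C could account for the values, and it was the only explanation tested whose values were there. In OMC the neighbours were raised as well, by 0.37 ± 0.07 in G2.

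The run around CDC50 next to ARS317 lay below the run around ARE1 in OC in G2, by −0.21 ± 0.06, and above it in MC2A in G2, by 0.21 ± 0.04 (exact p = 0.0286, 4 arrays each). The order was not the same throughout MC2A. There the difference was −0.16 ± 0.06 at 35 °C, 0.072 ± 0.005 at 23 °C (2 arrays each) and 0.29 ± 0.18 after G1 release (4 arrays). A bias fixed by the array print was excluded as the whole cause on the print runs shared by these groups. There the 2 pairs of OC and MC2A arrays differed by 0.302 and 0.437. The other print runs did not hold arrays of both groups, so a print bias was not excluded for them. Whether forks from ARS317 alone could give the OC pattern cannot be told apart from a further start site, because MC2A cdc7-1 at 35 °C, without a rise in the ARS317 region, showed nearly the same difference between the runs, leaving −0.027 with a joint standard deviation of 0.131. The 2 arrays of the ARS317 deletion strain had the ARE1 run at 0.19 ± 0.11, which did not pass the test (limma adjusted p = 0.168).

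The move from G2 to G1 release had different effects in the 3 strains. For each pair of strains, their mean stage effect was taken off and the stages were then permuted within strains (4900 permutations, BH over 9). Because that effect was estimated from the same arrays, these p values are approximate. For the ARS317 region the effects differed by −0.743 between OMC and OC and by −0.573 between OMC and MC2A (permutation p = 4.1e-04 and BH 6.1e-04 for each), and by 0.169 between OC and MC2A (permutation p = 0.0359). For the spread they differed by −0.043 (permutation p = 0.0065, BH 0.0073), 0.125 and 0.168 in the same order, and for the correlation with A364a S phase by 0.168 (permutation p = 0.0024, BH 0.0031), 0.384 and 0.216. Within the batch shared by both strains and stages the correlations were 0.41 and 0.09 in OMC and 0.40 and 0.12 in OC, so the difference of 0.168 rested largely on other arrays. Among these were the dye-swapped OMC arrays (0.549 and 0.552) and OMC replicates 3 and 4 in G2 (0.024 and 0.021). The share of each was not tested. The 4 values without a p had the same p as the comparison of OMC with OC in the ARS317 region. The effect of cdc7-1 differed between 35 and 23 °C by −0.392 at the ARS317 region and by −0.272 at the HMRA1 elements, by camera with an estimated correlation.

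Among all groups of 4 values tested, 7, or 5.3%, had an array far from the other 3, and chance gives about 1 in 20. They were the CDC6 ORF in OMC with re-replication in S phase (replicate 3, −0.052 against −0.129 to −0.117), chromosome XI in OMC in S phase (replicate 3, −0.110 against −0.003 to 0.000) and the elements beside early origins in the same group (replicate 4, 0.054 against 0.295 to 0.333). In OC in G2 they were the centromere-proximal elements (replicate 1, −0.012 against 0.002 to 0.004) and those beside late origins (replicate 4, 0.051 against −0.006 to −0.002). The engineered loci gave replicate 3 of OC after G1 release (0.092 against 0.180 to 0.184) and replicate 3 of MC2A in G2 (0.049 against −0.010 to −0.007).

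Chance was tested for each count by counting called runs over all 35 splits of each pair of groups of 4. The real split gave more than any other, 1 of 35, in 9 comparisons. That is the smallest share the test can give, so it argues against chance for arrays as units without excluding it. OMC in S phase shared no batch with A364a or with induced OMC, so in those comparisons the real split was also a split by batch. Arrays partly share DNA preparations, which the labels do not identify, so chance between preparations was not excluded. The margin was narrowest for A364a and S288c, where 0.34% of runs were called with the batch as a fixed block. The counts, real and highest other, were 193 and 168 for A364a and S288c, 321 and 128 for OMC and A364a in S phase, 500 and 275 for OMC S phase with and without re-replication, and 805 and 521 for the stages of OMC. For the stages of OC the real count was 604 and for OC and OMC in G2 it was 403, and no other split reached them. The pairs were 493 and 200 for MC2A and OMC in G2, 548 and 215 for OC and OMC after G1 release, and 830 and 544 for MC2A and OMC after G1 release. For the stages of MC2A the real count was 0 (limma, 39 at unadjusted p under 0.05), which all 35 splits reach by necessity, so that test says nothing on chance.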

How the results depend on the processing

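Runs of 3 and 10 ORFs, elements on at least 45 arrays, averaging within a batch, the fixed batch block outside cdc7-1 at 35 °C, leaving out chromosome XI, leaving out the outermost 3 runs of each arm and parts of the OMC G1-release arrays were chosen after the data were seen. Of the percentages of runs called, 378 stayed within 1.5 times and 32 did not, and the cause was not tested. Of 400 list medians with an array left out, 31 changed sign, at most from −0.080 to 0.045 (mitochondrial, OC after G1 release), in lists that did not pass with the estimated correlation. None of the 10 ARS317 region differences passed in the main analysis, and all 20 alternative values missed the threshold too. The check flagged a change of direction only where the main difference had passed, so it says nothing on direction here. Windows in kb, peaks and elements on all 50 arrays (36 runs left) were not run, the hybridizations are partly technical repeats, and signal over background limits faint elements to an unknown degree. No paired analysis was possible because the labels give no replicate numbers, except through hybridization batches shared between groups, which the batch blocks and the differences within batches used.

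Called runs fell to 0% in the ARS317 deletion and MC2A 35 °C profiles with the print run as covariate, and were 0.93% in MC2A at 23 °C and 1.18% between the MC2A stages. For these profiles the covariate fit gave the level on a print run that none of their arrays used. Their lower shares therefore do not show a print effect. With the batch as random block they were 0.84% in MC2A at 35 °C, 0.25% between the MC2A stages and 0.17% for cdc7-1 at 35 °C. As a fixed block it gave 0.34% between the wild types, 4.12% between the MC2A stages, 1.26% for cdc7-1 at 35 °C and 1.18% for the difference of the differences. Between the wild types and between the MC2A stages, the fixed block left a comparison of 1 array of each group in the shared batch. The compared groups alone gave 0.67% between the MC2A stages, 2.02% for the ARS317 deletion, 0.76% for cdc7-1 at 35 °C and 0.84% for the difference of the differences. A dye term gave 5.38% in OC and 5.81% in MC2A in G2. Elements on at least 45 arrays gave 2.78% in OC in G2 and 0.09% for the deletion, batch averages 0.25% for the deletion, runs of 10 ORFs 0.83% in MC2A at 35 °C, and runs of 3 ORFs 0.05% in cdc7-1 at 35 °C and 0.15% for the deletion. Leaving out an array gave 0 to 0.08% in the deletion profile, 0.08 to 0.67% for the deletion against MC2A, 0 to 0.26% in MC2A at 35 °C and 0 to 0.08% between the MC2A stages, where a lone remaining array was assumed to vary like the other groups.

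As the median over elements the ARS317 region level was −0.23 in S288c, 0.44 in OC after G1 release, 0.27 in MC2A at 35 °C and 0.60 at 23 °C. From YCR094W to YCR100C it was −0.29 in S288c, 0.80 in OMC in G2, 0.31 in OC after G1 release, −0.0126 in the deletion, 0.26 in MC2A at 35 °C, 0.60 at 23 °C and 0.71 with cdc7-1 at 23 °C. With runs of 10 ORFs the spread was 0.19 in OMC in S phase, 0.0656 in OC in G2, 0.0541 in MC2A in G2, 0.0518 in the deletion, 0.0547 in MC2A at 35 °C and 0.0316 with cdc7-1, and 0.0655 at 23 °C and 0.0696 with cdc7-1. With runs of 3 it was 0.0800 in OC in G2, 0.0663 in MC2A in G2, 0.0534 in MC2A after G1 release, 0.0665 in the deletion, 0.0786 in MC2A at 35 °C and 0.0506 with cdc7-1, and 0.0791 at 23 °C and 0.0843 with cdc7-1. Without the outermost 3 runs it was 0.25 in OMC in G2. Without chromosome XI it was 0.20 there and 0.23 in OC after G1 release. The spread difference between the MC2A stages passed with runs of 10 ORFs (−0.0151), and the correlation difference between OC and OMC after G1 release missed there (−0.0761). That between OC and OMC in G2 missed without the outermost 3 runs (0.0657) and without chromosome XI (0.0667). The profiles of A364a S phase and MC2A after G1 release passed without the outermost 3 runs (0.089) and ranged from 0.0494 to 0.0975 with an array left out.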

Other observations

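Apart from those of the subtelomeric list and of the correlations between group profiles, the tests in this part were chosen after the results were seen. Chromosome ends set the stages of re-replication apart. Without chromosome XI, the outermost 3 runs of each arm stood 0.21 ± 0.03 log2 above the other runs in OMC in G2 and 0.20 ± 0.01 below them after G1 release (exact p = 0.0286, BH 0.0357 over 10 tests, 4 arrays each). The subtelomeric list fixed in advance did not pass in either stage (adjusted p = 0.651 and 0.794 with an estimated correlation). In OMC in G2, 31 of 52 end runs were called higher and 5 lower, against 197 and 213 of 1071 elsewhere. After G1 release, 10 end runs were higher and 35 lower. The end runs of YCL076W and GIT1 stood at 0.95 and 0.77 in G2, and those of MAN2 and MAL31 at −0.80 and −0.78 after release. In OC the ends stood at 0.01 ± 0.01 in G2 and −0.13 ± 0.00 after release (exact p = 0.0286, BH 0.0357), with 27 of 52 end runs lower after release. In MC2A they stood at −0.00 ± 0.03 and 0.01 ± 0.01 (exact p = 0.571).

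In wild-type S phase the ends stood at −0.12 ± 0.02 in S288c, where 32 of 52 end runs were lower, and at −0.10 ± 0.03 in A364a, where 25 were. In OMC in S phase they stood at −0.01 ± 0.02, which was higher than in A364a (exact p = 0.0286, BH 0.0357 over 10 tests), and with re-replication at −0.07 ± 0.03. Between the profiles, OMC with re-replication in S phase correlated with OMC after G1 release at r = 0.70 and with OC after G1 release at r = 0.62 over 1185 runs. Each shift p was 1e-04, the smallest possible with 10000 shifts (BH 1.8e-04 over 105 pairs), and runs are not independent replicates. OMC with re-replication in S phase and OMC in G2 correlated at r = 0.15 (shift p = 0.0249, BH 0.0319).

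The 4 OMC arrays with re-replication in S phase fell in pairs by batch. The ARS317 region stood at 0.224 and 0.239 on replicates 1 and 2, and at −0.0553 and −0.122 on replicates 3 and 4. The spread was 0.272 and 0.274 on the former pair and 0.360 and 0.354 on the latter. Among the S288c arrays, the 2 whose titles name hydroxyurea and the 2 whose titles name a time had mean profiles that correlated at r = 0.95, with centromere-proximal medians of 0.49 and 0.48 and mitochondrial medians of −1.25 and −0.43. Their mean correlations with the A364a S-phase profile were 0.86 and 0.93, so the hydroxyurea arrays were less like A364a. In the deposited ratios, mitochondrial DNA in S phase stood at 0.78 ± 0.27 of the reference in S288c, 0.94 ± 0.02 in A364a, 0.89 ± 0.05 in OMC and 1.05 ± 0.21 in OMC with re-replication. In the other 11 groups the means ran from 1.49 ± 0.13 in OC in G2 to 2.48 ± 0.53 in OC after G1 release. Because the scale differs between groups, the higher ratios do not show a gain of mitochondrial DNA. In OC after G1 release, with a DNA content of 2.6, the mitochondrial median was −0.08 log2 relative to the array median.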
